A study of Mus musculus with 6 samples.

How the data were processed

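The series measured RNA from 6 libraries of C2C12 cells, a mouse myoblast line. Of these, 3 came from cells transfected with a control siRNA (siControl 1 to 3) and 3 from cells transfected with an siRNA against Usf2 (siUsf2 1 to 3), with groups and replicate numbers taken from the sample titles. Total RNA was extracted with TRIzol after lipofectamine transfection, per the labels' protocols. The labels do not say whether replicates of a group were separate cultures. The p-values therefore measure the spread between these samples, which may be technical.

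The deposited table of read counts holds whole-number counts per Ensembl gene identifier, 1 column per library, with no normalization. Per the submitters' processing notes, the genome build was mm10 and the tools named were FastQC, Trimmomatic, HISAT2, featureCounts and DESeq2. Their versions, roles, order, strand setting and gene annotation are not given in the sources used here. A second deposited table is named for TPM, a unit scaled by gene length, but its values are CPM, counts scaled to a fixed library total: each value equals the deposited count scaled by its column total, with no gene length in it. Dividing each deposited CPM value by the worth of 1 read gave whole numbers for 100% of values within a tolerance of 1e-06, and these equalled the deposited counts in every library. The settings meant for TPM were therefore run on log2(CPM + 1) and log2(CPM + 0.1).

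The count table holds 55414 identifiers, of which 25980 were at 0 in all 6 libraries. Gene symbols, biotypes and coordinates came from the GENCODE M21 annotation of GRCm38, the assembly also called mm10, matched by gene identifier. Of the identifiers, 52133 were found there, and the remaining 3281 carry no symbol here. Where 2 identifiers shared a symbol, the one with fewer counts kept its identifier in its name. Total counts ranged from 3414565 to 17715250 per library, so a count of 0 allows up to 0.169 CPM (3 counts) in the deepest library and up to 0.879 CPM in the shallowest. Intervals on single-library values are exact Poisson 95% intervals, and they and these limits cover counting error only. Replicate pairs within a group differed by more than counting noise, so none was treated as a repeat of another (chi-square per degree of freedom 4.38 to 13 within groups, without the library labelled siUsf2 3).

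The main comparison of siUsf2 with siControl used edgeR 4.0.16 in R 4.3.3 on all 6 libraries: filterByExpr, TMM normalization, and the robust quasi-likelihood test (glmQLFit, glmQLFTest), two-sided, with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p below 0.05. The 19 gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists with at least 5 tested members. Camera with an estimated correlation and fry were run beside it. The tests, lists, rule for named genes and the settings listed as chosen with them were fixed before the data were examined.

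The named genes follow a rule: Usf2 and Usf1; in each direction the 6 called genes with the smallest p and the 5 with the largest fold among those with a mean log2 CPM of at least 3 and no overlap between groups; and up to 4 members of each list by p. Predicted gene models were left out of these picks. Some genes that the rule picks are not reported here. Because the library labelled siUsf2 3 stood apart in depth, pseudogene share and correlation, the comparison was repeated without it, with the same rule for named genes. Leaving out each library was planned, but the use of this 5-library comparison (3 siControl, 2 siUsf2) as a second starting point was chosen after seeing the data, when its Usf2 level was also known.

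Other settings tried, chosen with the tests above, were RLE, library-size and upper-quartile normalization, DESeq2 1.42.0, limma-voom, the test without robust estimation, limma on log2 CPM, no filter, filters of 1 CPM or 50 counts in 3 libraries, a replicate block, an adjusted p below 0.01, and each library left out. Sample quality weights, reads recovered from the CPM table, and the addition of pseudogene counts to parent genes were added after seeing the data. For the last, transcripts of pseudogenes were aligned to transcripts of protein-coding genes with minimap2 2.31 (at least 90% identity, 50% coverage and 150 matching bases), which paired 4688 pseudogenes with 1676 parents.

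The test was tried on simulated counts drawn from the means and library sizes of the real libraries. All genes and libraries shared 1 dispersion, 0.16 for the 6 libraries and 0.0086 for the 5. Neither a spread of dispersion between genes nor a library that stands apart was simulated, so the shares below are a rough guide. With the settings of all 6 libraries (16568 genes), 0% of genes changed 1.5-fold, 0% of genes changed 2-fold and 50% of genes changed 4-fold were recovered, with 1 false call among 34. With the settings of the 5 libraries (17048 genes), the shares were 53.7%, 88.1% and 93.9%, with 11 false calls among 168.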

Results

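Gene expression was measured by RNA sequencing in C2C12 myoblasts, mouse muscle precursor cells that can leave the cell cycle and fuse into myotubes. Cells received an siRNA against Usf2, a basic helix-loop-helix leucine zipper transcription factor that binds E-box sequences, or a control siRNA. The comparison asks which genes differ when USF2 is knocked down, as the series states its aim. Each group has 3 libraries. Total counts were 14790997, 16006492 and 17715250 in siControl 1 to 3, and 15817183, 14932880 and 3414565 in siUsf2 1 to 3.

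Usf2 (ENSMUSG00000058239) lies on chromosome 7 at 30945248 to 30956803 (GRCm38, minus strand, 10 exons). Its level was 26.2 CPM (95% Poisson interval 23.6 to 28.9), 31.2 CPM (28.5 to 34) and 23.0 CPM (20.9 to 25.4) in siControl 1 to 3. It was 17.1 CPM (15.1 to 19.2) in siUsf2 1 and 15.3 CPM (13.4 to 17.5) in siUsf2 2, below every siControl library. The library labelled siUsf2 3 held 30.8 CPM (25.2 to 37.2), within the siControl range, so its Usf2 level goes against its label. Over all 6 libraries Usf2 was 26.8 ± 4.11 CPM in siControl and 21.1 ± 8.44 CPM in siUsf2 (SD, n = 3 each), a log2 fold change of -0.40 (SE 0.28, edgeR adjusted p = 0.702) that did not pass the test. Without the library labelled siUsf2 3, Usf2 was lower, at a log2 fold change of -0.74 (SE 0.14, edgeR adjusted p = 6.43e-04), to 16.2 ± 1.23 CPM (SD, n = 2). The pseudogene Usf2-ps1 had 97, 152 and 75 counts in siControl 1 to 3, 66 and 61 in siUsf2 1 and 2, and 0 in the library labelled siUsf2 3. Usf1, the paralog of Usf2, had a log2 fold change of -0.25 in the 5 libraries (SE 0.13, edgeR adjusted p = 0.234). Over all 6 libraries its sign turned, to 0.31 (SE 0.41, edgeR adjusted p = 0.857). The library labelled siUsf2 3 held 68.8 CPM of Usf1, against 26.0 to 35.6 CPM in siControl.

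The library labelled siUsf2 3 also differed from the other 5 in ways other than its Usf2 level. It detected 17404 genes, against 23515 to 24501 in the others and 20697 in siUsf2 1 thinned to its total. Pseudogenes took 0.970% of its counts, against 14.0% to 15.3%, and ribosomal protein genes 3.15%, against 0.186% to 0.245%. Across genes, which are not independent replicates, its log2(CPM + 1) values correlated with the others at r = 0.884 to 0.888, while the other pairs ranged from 0.991 to 0.996. Its log2 ratio to siUsf2 1 and 2 also rose with the number of exons per transcript length, with medians of -0.05, -0.04, 0.11 and 0.38 over 4 equal groups of genes ordered by it, so list values in this library include that shift. Tpt1, an abundant gene with 5 pseudogene copies, had 18.5 to 26.2 CPM in the other libraries and 2981 CPM in this one, whereas Tpt1 and its pseudogenes together held 3131 to 3310 CPM and 3113 CPM.

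**Figure D1:**
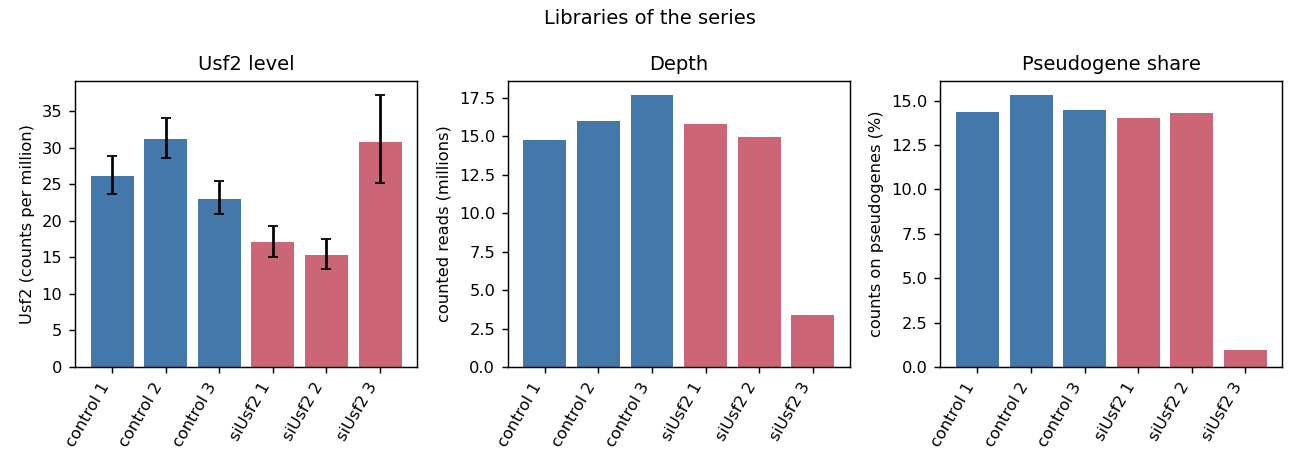
Usf2 level in CPM with exact 95% Poisson intervals, total counted reads, and the percentage of counts on pseudogenes, for each library (siControl in blue, siUsf2 in red). The library labelled siUsf2 3 has 3414565 counts, 0.970% of counts on pseudogenes and a Usf2 level of 30.8 CPM, where siUsf2 1 and 2 have 17.1 and 15.3 CPM.

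**Figure D2:**
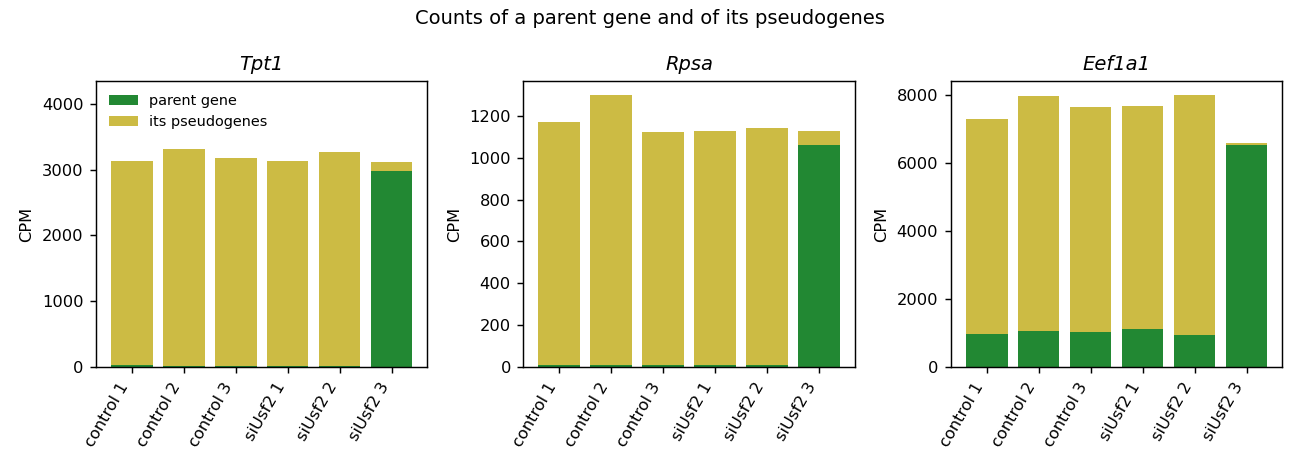
CPM of 3 genes (green) and of their annotated pseudogene copies (yellow), stacked, for each library. In the library labelled siUsf2 3 the counts sit on the parent gene (Tpt1 at 2981 CPM), and in the other 5 libraries mainly on the pseudogenes, while the sum stays near 3113 to 3310 CPM for Tpt1.

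With all 6 libraries, 7 genes fell in siUsf2, each at least 2-fold. Smyd1, a muscle methyltransferase needed for sarcomere assembly, fell by 1.76 on the log2 scale (SE 0.10), from 67.4 ± 1.96 to 20.4 ± 2.11 CPM (SD, n = 3 each). The log2 fold change was -2.24 (SE 0.15) for Tmem182, a membrane protein of muscle, -1.95 (SE 0.15) for Klhl41, a sarcomere-associated kelch protein, and -2.35 (SE 0.18) for Hrc, a calcium-binding protein of the sarcoplasmic reticulum. Myh6, a cardiac myosin heavy chain, fell by 4.35 (SE 0.33) from a low level of 4.92 ± 0.845 CPM. It was -1.15 (SE 0.08) for Car3, a carbonic anhydrase abundant in muscle, and -1.41 (SE 0.09) for C1qtnf3, a secreted protein. Each value in the library labelled siUsf2 3 lay below every siControl library for these genes, with Smyd1 at 22.6 CPM and Klhl41 at 55.4 CPM there. The test that called these genes included that library, so their low level in it is no separate support.

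The edgeR adjusted p was 0.0392 for Smyd1, Car3, C1qtnf3 and Tmem182 and 0.0490 for Klhl41, Myh6 and Hrc, among 16662 genes tested. The edgeR count of higher genes was 0, with 1753 genes in either direction at an unadjusted p below 0.05; DESeq2 called 288 higher and 433 lower, and limma-voom 19 higher and 87 lower. With upper-quartile normalization edgeR called no gene in either direction (1835 at an unadjusted p below 0.05). Without siControl 1, siControl 2, siControl 3, siUsf2 1 or siUsf2 2 in turn, edgeR called 0 genes in each direction (1065 to 1485 at an unadjusted p below 0.05). Without the library labelled siUsf2 3 it called 855 higher and 1102 lower.

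The 5-library comparison, of siUsf2 1 and 2 with siControl 1 to 3, therefore carries most of the calls described below. Among 17217 genes tested, 855 rose and 1102 fell, with 111 and 248 of them at least 2-fold, and all 7 genes of the 6-library comparison were among those called. Predicted gene models made up 110 of the higher and 160 of the lower genes, and pseudogenes 44 and 157, with 2763 pseudogenes tested. The biological coefficient of variation was 9.25%, against 40.0% with all 6 libraries. Upper-quartile normalization gave 1124 higher and 900 lower, 55.5% higher against 43.7%. In these 5 libraries reads of some abundant genes, such as Tpt1, sat mainly on their pseudogenes. Values of single genes with pseudogene copies are therefore uncertain here. With pseudogene counts added to parent genes, 879 genes rose and 1137 fell. The counts moved with single libraries: 469 higher and 586 lower without siControl 1, 485 and 659 without siControl 2, 1596 and 1964 without siControl 3, 349 and 519 without siUsf2 1, and 477 and 694 without siUsf2 2, where the remaining siUsf2 library is assumed to vary like the siControl libraries.

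Most measured genes of muscle differentiation fell. Of 29 measured contractile and muscle differentiation genes, 27 fell and 2 did not pass in the 5 libraries by edgeR (28 fell when adjusted over the list alone), with a median log2 fold change of -2.09. Acta1, skeletal muscle alpha-actin, went from 1657 ± 121 CPM in siControl (SD, n = 3) to 392 ± 24.4 CPM in siUsf2 1 and 2 (SD, n = 2), a log2 fold change of -2.09 (SE 0.10, edgeR adjusted p = 1.44e-15). The log2 fold change was -3.20 (SE 0.12, edgeR adjusted p = 2.17e-15) for Myh3, the embryonic myosin heavy chain, -2.14 (SE 0.10) for Tnni1, slow troponin I, and -3.07 (SE 0.15) for Myl4, an embryonic myosin light chain. Outside the list it was -2.47 (SE 0.11) for Mybph, a myosin-binding protein, and -3.37 (SE 0.23) for Cacna1s, the voltage sensor of excitation-contraction coupling. The members that did not pass were the giant sarcomere proteins Neb and Ttn, chosen after their values were seen, at log2 fold changes of -1.38 and -0.45.

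The list was lower by camera (adjusted p = 6.87e-31; adjusted p = 0.14 with an estimated correlation; fry adjusted p = 0.00195). The library labelled siUsf2 3 had a list median of -0.77 against the siControl mean (log2), or -0.92 with pseudogene counts added to parent genes, with Acta1 at 718 CPM and Myh3 at 200 CPM, between siControl and siUsf2 1 and 2. In that library 5 of the 29 members lay above every siControl library, against the direction of the list, and 21 below. The 5 were Mylpf at 187 CPM, Myl1 at 123 CPM, Tnnt1 at 192 CPM, Tnnt2 at 103 CPM and Tnnt3 at 92.8 CPM, chosen after their values were seen. With pseudogene counts added, Myl1 held 165 CPM there, below the 363 to 413 CPM of siControl, and the other 4 remained above. With all 6 libraries no member passed over all genes, 19 of 28 fell when adjusted over the list alone, and the list was lower by camera (adjusted p = 5.82e-18; adjusted p = 0.214 with an estimated correlation).

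Of 15 measured myogenic regulators, 7 fell, 1 rose and 7 did not pass in the 5 libraries (8 fell and 1 rose when adjusted over the list alone), with a median log2 fold change of -0.24. Mymk (myomaker) and Mymx (myomixer), the fusion proteins of myoblasts, had log2 fold changes of -2.39 (SE 0.10, edgeR adjusted p = 7.3e-17) and -1.56 (SE 0.13, edgeR adjusted p = 3.58e-10). Myog, a transcription factor of terminal differentiation, was at -1.77 (SE 0.10, edgeR adjusted p = 6.44e-13), from 1037 ± 119 to 306 ± 33.8 CPM (SD, n = 3 and n = 2), and Mef2a, a partner of the myogenic factors, at -0.52 (SE 0.09). Myf5, a factor of undifferentiated myoblasts chosen after its values were seen, was the member that rose, by 0.37 on the log2 scale (edgeR adjusted p = 0.0326). The list was lower by camera (adjusted p = 5.92e-04; adjusted p = 0.14 with an estimated correlation). Its median was -0.23 in the library labelled siUsf2 3, and with all 6 libraries it was also lower (camera adjusted p = 7.63e-04; adjusted p = 0.104 with an estimated correlation), with 5 members that fell when adjusted over the list alone.

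Most measured interferon response genes fell as well. Of 25 measured members, 20 fell, 1 rose and 4 did not pass in the 5 libraries by edgeR (23 fell and 1 rose when adjusted over the list alone), with a median log2 fold change of -1.40. Ifit3, an interferon-induced antiviral protein, was at a log2 fold change of -3.10 (SE 0.21, edgeR adjusted p = 2.26e-11), from 25.3 ± 4.36 CPM in siControl to 2.98 ± 0.995 CPM in siUsf2 1 and 2 (SD, n = 3 and n = 2). It was -2.16 (SE 0.23) for Irf7, a transcription factor of the type I interferon response, and -2.21 (SE 0.21) for Oasl2, an antiviral protein. The member that rose was the chemokine Ccl5, chosen after its values were seen, at 1.53 on the log2 scale (SE 0.24, edgeR adjusted p = 4.70e-05). The list was lower by camera (adjusted p = 8.91e-15; adjusted p = 0.14 with an estimated correlation; fry adjusted p = 0.00816). The library labelled siUsf2 3 had a list median of -1.59 against the siControl mean, with Ifit3 at 2.34 CPM. With all 6 libraries no member passed over all genes, 20 fell and 1 rose when adjusted over the list alone, and the list was lower (camera adjusted p = 3.47e-18; adjusted p = 0.0863 with an estimated correlation).

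Of 25 measured genes of G2/M and mitosis, 12 rose and 13 did not pass in the 5 libraries by edgeR (18 rose when adjusted over the list alone), with a median log2 fold change of 0.34. Top2a, the topoisomerase that decatenates chromosomes, rose from 217 ± 12.1 to 309 ± 13.4 CPM (SD, n = 3 and n = 2; log2 fold change 0.50, SE 0.09, edgeR adjusted p = 1.47e-04). Hmmr, a spindle protein, Bub1, a spindle checkpoint kinase, and Cenpe, a kinetochore motor, rose by 0.58 (SE 0.10), 0.62 (SE 0.11) and 0.55 (SE 0.10). The list was higher by camera (adjusted p = 1.15e-09; adjusted p = 0.14 with an estimated correlation). In the 6-library comparison it was also higher (camera adjusted p = 1.41e-12; adjusted p = 0.0863 with an estimated correlation), with 10 members that rose when adjusted over the list alone, and its median in the library labelled siUsf2 3 was 0.55, or 0.43 with pseudogene counts added to parent genes.

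Of 25 genes of G1/S and DNA replication, Prim1, a DNA primase subunit, was the member called over all genes in the 5 libraries (log2 fold change 0.43, SE 0.14, edgeR adjusted p = 0.0431), and no member passed when adjusted over the list alone. Its call ended without siControl 2 (adjusted p = 0.166), without siUsf2 1 (adjusted p = 0.18), without siUsf2 2 (adjusted p = 0.186) and with DESeq2 (adjusted p = 0.0985). The list median was 0.21 and the list was higher by camera (adjusted p = 7e-04; adjusted p = 0.14 with an estimated correlation). In the 6-library comparison it was higher (camera adjusted p = 6.94e-07; adjusted p = 0.214 with an estimated correlation), and its median in the library labelled siUsf2 3 was 0.56, or 0.34 with pseudogene counts added to parent genes.

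Among 20 p53 target genes, Cdkn1a, the cyclin-dependent kinase inhibitor p21 that accompanies cell cycle exit of myoblasts, was at a log2 fold change of -1.13 (SE 0.09, edgeR adjusted p = 7.6e-11), from 714 ± 42.9 to 328 ± 0.229 CPM (SD, n = 3 and n = 2). Zmat3, an RNA-binding protein, Ccng1, a cyclin, and Trp53inp1, a p53 cofactor, rose by 0.60 (SE 0.09), 0.56 (SE 0.09) and 0.56 (SE 0.09), and in all 4 members rose, 1 fell and 15 did not pass (5 rose and 1 fell when adjusted over the list alone). The p53 list did not pass camera (adjusted p = 0.257), with a median of -0.01, a mean of 0.09 and the direction of the test upward. Over all 6 libraries no member passed over all genes, 1 fell when adjusted over the list alone, and the list did not pass (median 0.12, camera adjusted p = 0.136). Cdkn1a was at 396 CPM in the library labelled siUsf2 3, below every siControl library, and Trp53inp1 at 98.1 CPM there, within the siControl range.

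Of 28 extracellular matrix and TGF-beta response genes, 9 rose and 19 did not pass in the 5 libraries by edgeR (11 rose and 3 fell when adjusted over the list alone), with a median log2 fold change of 0.15. Timp3, a metalloproteinase inhibitor, rose from 71.1 ± 10.1 to 158 ± 0.520 CPM (SD, n = 3 and n = 2; log2 fold change 1.13, SE 0.10, edgeR adjusted p = 3.88e-09). Loxl2, a collagen cross-linking enzyme, rose by 0.88 (SE 0.12), and Cnn1, smooth muscle calponin, by 2.10 (SE 0.38) from a low level of 0.973 ± 0.452 CPM. The list was higher by camera (adjusted p = 0.00409; adjusted p = 0.14 with an estimated correlation), a call that ended without siUsf2 2 (adjusted p = 0.0706). With all 6 libraries it was higher (camera adjusted p = 1.11e-05; adjusted p = 0.2 with an estimated correlation), with 2 members that rose when adjusted over the list alone. Its median was 0.37 in the library labelled siUsf2 3.

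Outside the lists, the genes that rose with the smallest p in the 5 libraries were led by Il33, an alarmin cytokine, from 33.5 ± 2.39 to 85.7 ± 0.332 CPM (SD, n = 3 and n = 2; log2 fold change 1.34, SE 0.10, edgeR adjusted p = 2.11e-11). Actg2, the enteric smooth muscle actin, rose by 1.1 (SE 0.09), Car9, a carbonic anhydrase induced by hypoxia, by 1.38 (SE 0.12), Ptgs2, the inducible cyclooxygenase, by 1.23 (SE 0.11) and Psrc1, a spindle protein, by 1.29 (SE 0.13). The larger increases at a mean log2 CPM of at least 3 were in Pappa, a metalloproteinase that cleaves insulin-like growth factor binding proteins, at 1.52 (SE 0.17), Plek, a kinase C substrate, at 1.45 (SE 0.16) and Lrrc15, a membrane protein of fibroblasts, at 1.38 (SE 0.15). In the library labelled siUsf2 3, Il33 was at 63.6 CPM, Car9 at 53.9 CPM and Actg2 at 158 CPM, each above every siControl library.

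**Figure D3:**
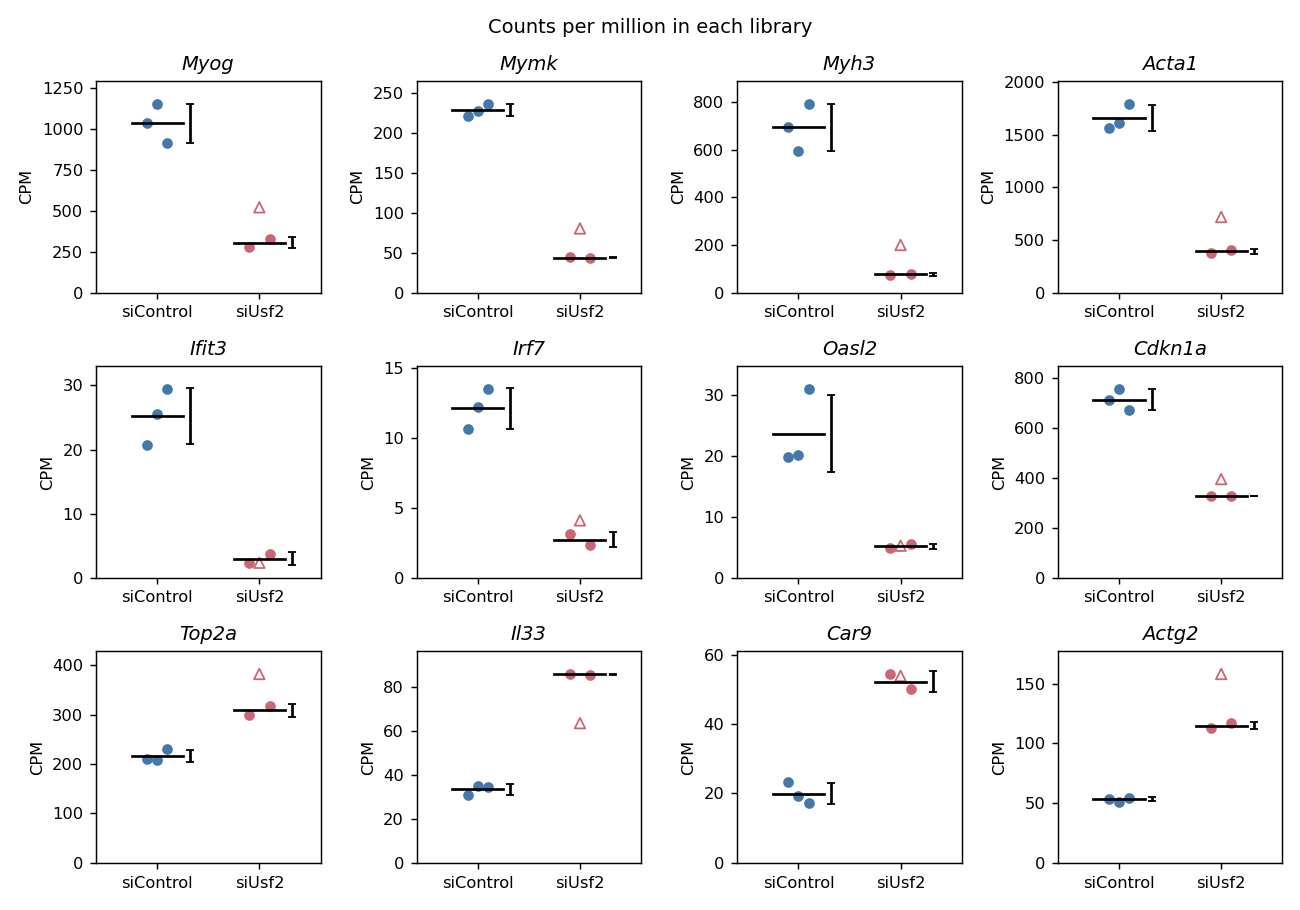
CPM of 12 genes in each library, with filled points for siControl 1 to 3 (blue) and siUsf2 1 and 2 (red), and an open triangle for the library labelled siUsf2 3. Black lines are means and error bars SDs, both without the triangle; Myh3 is at 694 CPM in siControl, 76.2 CPM in siUsf2 1 and 2 and 200 CPM in the library labelled siUsf2 3.

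Of 24 ATF4 and unfolded protein response genes, 10 fell and 14 did not pass in the 5 libraries by edgeR (11 fell and 2 rose when adjusted over the list alone), with a median log2 fold change of -0.31. The log2 fold change was -0.99 (SE 0.10, edgeR adjusted p = 8.27e-08) for Slc7a5, an amino acid transporter, -1.26 (SE 0.14) for Trib3, a pseudokinase, -0.87 (SE 0.10) for Mthfd2, a mitochondrial folate enzyme, and -0.64 (SE 0.09) for Herpud1, a protein of endoplasmic reticulum degradation. The list was lower by camera (adjusted p = 5.92e-04; adjusted p = 0.176 with an estimated correlation). It was not called over all 6 libraries (camera adjusted p = 0.0975), but it was lower there with limma-voom (adjusted p = 0.00767), with sample quality weights (adjusted p = 2.63e-04), with pseudogene counts added (adjusted p = 0.00659) and without the library labelled siUsf2 3. Its median in that library was 0.03, or -0.05 with pseudogene counts added to parent genes.

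Of 27 nuclear genes of mitochondrial respiration, 6 fell and 21 did not pass in the 5 libraries by edgeR (10 fell when adjusted over the list alone), with a median log2 fold change of -0.25. The log2 fold change was -0.42 (SE 0.09, edgeR adjusted p = 0.00264) for Uqcrfs1, a complex III subunit, and -0.34 (SE 0.08, edgeR adjusted p = 0.00701) for Atp5a1, an ATP synthase subunit. Their calls ended without siUsf2 1 (adjusted p = 0.0502 and 0.175), and that of Atp5a1 also without siUsf2 2 (adjusted p = 0.0654). The list was lower by camera (adjusted p = 1.89e-04; adjusted p = 0.235 with an estimated correlation). With all 6 libraries its median was 0.35 and it was not called (camera adjusted p = 0.349), although it was called higher without siUsf2 1 (adjusted p = 0.0261) and without siUsf2 2 (adjusted p = 0.0287). In the library labelled siUsf2 3 its median was 1.03 (0.82 with pseudogene counts added to parent genes), a direction opposite to that of siUsf2 1 and 2. Among 15 mitochondrially encoded transcripts no member passed over all genes or when adjusted over the list alone, with a median of 0.03 and a camera adjusted p of 0.381 (0.0237 without siControl 3).

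Of 25 genes of glycolysis and fatty acid synthesis, 4 rose, 2 fell and 19 did not pass in the 5 libraries by edgeR (7 rose and 2 fell when adjusted over the list alone), with a median of 0.10. Txnip, an inhibitor of glucose uptake, rose by 0.58 (SE 0.09, edgeR adjusted p = 1.81e-05) and Slc2a1, the glucose transporter GLUT1, by 0.47 (SE 0.09, edgeR adjusted p = 3.18e-04). Gapdh had a log2 fold change of -0.35, with an edgeR adjusted p of 0.0245 that became 0.125 without siControl 1 and 0.0549 without siControl 2. It was at -0.39 without siUsf2 1 and -0.31 without siUsf2 2. Its reads may be shared with pseudogene copies, and its value is uncertain. The list was higher by camera (adjusted p = 0.0389; adjusted p = 0.317 with an estimated correlation), a call that ended without siControl 3 (adjusted p = 0.124) and without siUsf2 2 (adjusted p = 0.208). It ended as well with fry (adjusted p = 0.0854), DESeq2 (adjusted p = 0.0757) and no low-count filter (adjusted p = 0.0918). Its median in the library labelled siUsf2 3 was 0.86, or 0.31 with pseudogene counts added to parent genes. Over all 6 libraries it was higher (camera adjusted p = 9.02e-05; adjusted p = 0.423 with an estimated correlation).

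**Figure D4:**
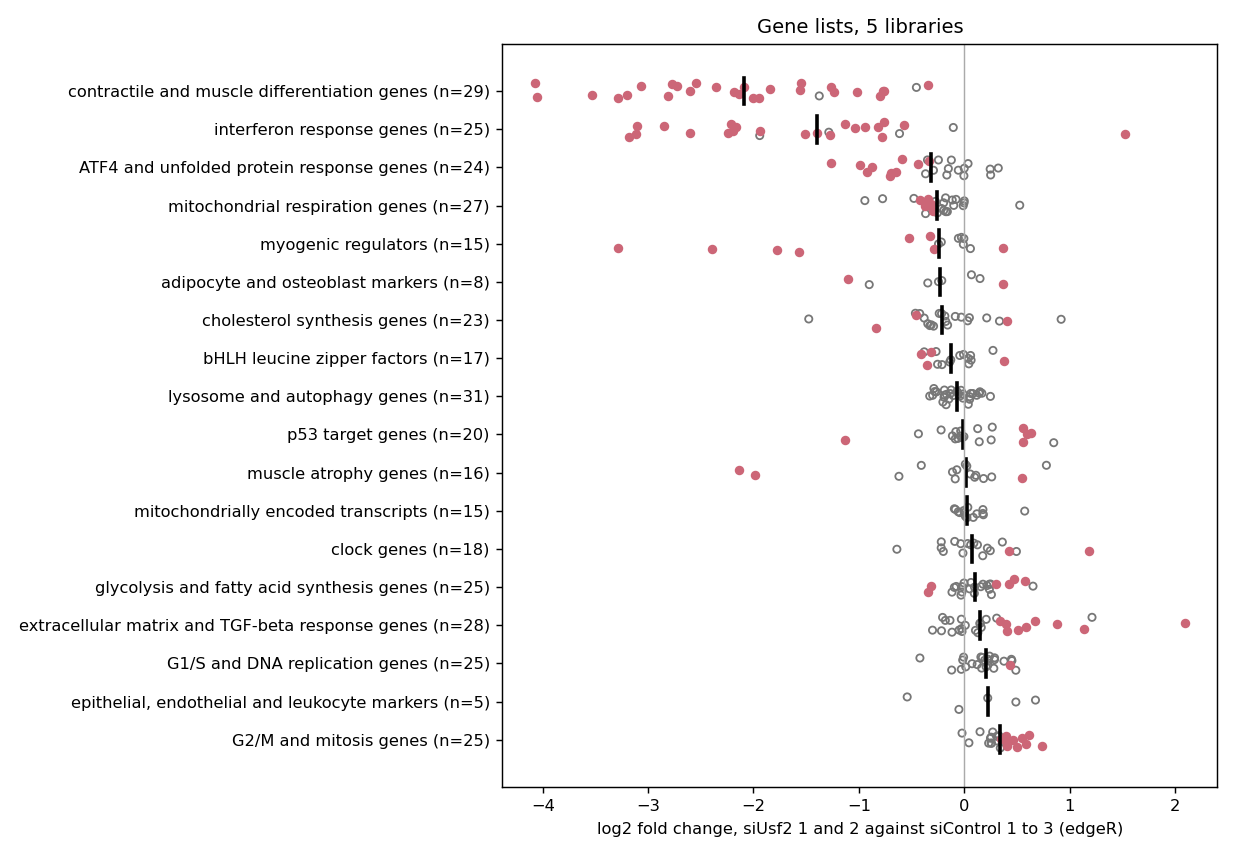
Log2 fold change of each measured member of the fixed gene lists, siUsf2 1 and 2 against siControl 1 to 3; filled red points were called by edgeR, open points were not, and black bars are list medians. The contractile and muscle differentiation genes have a median of -2.09 and the interferon response genes of -1.40, while G2/M and mitosis genes have a median of 0.34.

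The other lists did not pass camera in the 5 libraries. Cholesterol synthesis genes had a median of -0.21 (adjusted p = 0.07), with 1 of 23 members higher and 2 lower by edgeR (2 and 4 when adjusted over the list alone). This list was called lower without siControl 1 (adjusted p = 0.0387), without siUsf2 1 (adjusted p = 0.0478), with DESeq2 (adjusted p = 0.0359) and with no low-count filter (adjusted p = 0.0284). Of 17 basic helix-loop-helix leucine zipper factors, the family of USF2, 1 rose and 3 fell, the same numbers when adjusted over the list alone (median -0.13, camera adjusted p = 0.257). Mxi1, a MYC antagonist, rose by 0.38 (SE 0.10, edgeR adjusted p = 0.00796, against 0.147 without siUsf2 2). Mycl, a MYC family member, was at -0.41 (SE 0.10, edgeR adjusted p = 0.00832, against 0.0773 without siControl 1 and 0.218 without siUsf2 1). Srebf1, a regulator of lipid synthesis, was at -0.35 (adjusted p 0.0612, 0.0531, 0.11 and 0.143 without siControl 1, siControl 2, siUsf2 1 and siUsf2 2), and Srebf2, of cholesterol synthesis, at -0.31 (adjusted p 0.0912, 0.334 and 0.0568 without siControl 1, siUsf2 1 and siUsf2 2). Of 18 clock genes, 2 rose and 0 fell (the same when adjusted over the list alone; median 0.08, camera adjusted p = 0.257). They were Hlf, a clock output factor, at 1.19 (SE 0.16, edgeR adjusted p = 1.28e-05) and Per3, a period protein, at 0.42 (SE 0.10), the latter with an adjusted p of 0.154 without siUsf2 1.

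Of 16 muscle atrophy genes, 1 rose, 2 fell and 13 did not pass (1 and 3 when adjusted over the list alone). Trim63, a muscle ubiquitin ligase, was at a log2 fold change of -2.14 (SE 0.28, edgeR adjusted p = 1.62e-06) and Mt2, a metallothionein, at -1.98 (SE 0.42). Mt2 was at a low level of 3.84 ± 1.33 CPM in siControl (SD, n = 3), was at -2.81 without siUsf2 1 and -1.48 without siUsf2 2, and held 5.27 CPM in the library labelled siUsf2 3, above every siControl library. Bnip3, a mitophagy receptor, rose by 0.55 (SE 0.15, edgeR adjusted p = 0.0237, against 0.0799 without siControl 1 and 0.0806 without siControl 2). The list median of 0.02 differed in sign from its mean of -0.21 and from the downward direction of the test (camera adjusted p = 0.779). Of 31 lysosome and autophagy genes, none passed over all genes or when adjusted over the list alone (median -0.07, camera adjusted p = 0.257), with Gaa, the lysosomal alpha-glucosidase, at -0.26 (SE 0.09, edgeR adjusted p = 0.0647). Of 8 adipocyte and osteoblast markers, Lpl, lipoprotein lipase, rose by 0.36 (SE 0.09, adjusted p 0.0788 without siUsf2 1), and Cd36, a fatty acid transporter, was at -1.11 (SE 0.34) from a low level, with adjusted p of 0.0756, 0.0973, 0.108 and 0.142 without siControl 1, siControl 3, siUsf2 1 and siUsf2 2. The counts were the same when adjusted over the list alone (median -0.23, camera adjusted p = 0.444). Markers of epithelial, endothelial and leukocyte cells were at or below a few CPM where measured, except Cd14 at 19.9 ± 1.85 CPM in siControl and 19.4 ± 1.19 CPM in siUsf2 1 and 2 (SD, n = 3 and n = 2), and none of 5 passed over all genes or when adjusted over the list alone (median 0.22, camera adjusted p = 0.693). Only 3 replication-dependent histone genes were measured, too few for a list test; of these Hist1h1c, a linker histone, was at -0.71 (SE 0.10, edgeR adjusted p = 1.46e-05).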

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

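Alternatives to the 6-library comparison that were added after seeing the data are the sample quality weights, the reads recovered from the CPM table and the added pseudogene counts. For the 5-library comparison all alternatives were. Over all 6 libraries, the counts of lower genes (7 by edgeR as reported, each at least 2-fold) were 4 with RLE normalization, 3 with library size alone, 0 with upper-quartile normalization, 3 with limma on log2(CPM + 1) or log2(CPM + 0.1), 4 with a filter of 1 CPM and 4 with a filter of 50 counts, the same numbers at least 2-fold, and 0 at an adjusted p below 0.01. The count of higher genes was 0 in these settings, with 1450 to 1835 genes at an unadjusted p below 0.05. DESeq2 called 288 higher and 433 lower (58 and 184 at least 2-fold), limma-voom 19 and 87 (14 and 65), and edgeR without a filter 12 and 104 (10 and 79). Sample quality weights, which gave the library labelled siUsf2 3 a weight of 0.122, called 681 and 774 (92 and 221), and pseudogene counts added to parents 31 and 119 (15 and 83). With 1 library left out the counts ranged from 0 to 855 higher and from 0 to 1102 lower (0 to 111 and 0 to 248 at least 2-fold). The upper ends came from leaving out the library labelled siUsf2 3. Usf2 ranged from -0.736 to -0.225 (log2) with 1 library left out, and was -0.736 with quality weights (adjusted p = 0.014, where its alternatives ranged from 6.43e-04 to 0.969). Whether the replicate numbers pair the libraries could not be told. Same-numbered libraries had correlations of deviations from group means of -0.0739, -0.00488 and -0.0727, and no siControl library correlated best with its own number. The outlying library labelled siUsf2 3 dominates these deviations: siControl 1 gave -0.0739, -0.0709 and 0.0745 with siUsf2 1 to 3. In the 5 libraries the deviations of siUsf2 1 and 2 are opposite by construction. With the number as a replicate block, edgeR called 0 genes lower and 0 at least 2-fold over all 6 libraries (874 at an unadjusted p below 0.05), and 1719 higher and 2270 lower (195 higher at least 2-fold) in the 5 libraries. In the 5 libraries siControl 3 is the only library with its number, so the block sets it aside from the group comparison. The block ended the call of the glycolysis list there (camera adjusted p = 0.17). It added one for mitochondrially encoded transcripts (camera adjusted p = 0.043). Both calls also changed when siControl 3 was left out (camera adjusted p = 0.124 and 0.0237). In the 5 libraries an adjusted p below 0.01 left 398 higher and 540 lower, and the count of genes higher at least 2-fold (111 as reported) was 53 with DESeq2, 35 with a filter of 50 counts and 35 with limma on log2(CPM + 1). With 1 further library left out the counts ranged from 349 to 1596 higher, 519 to 1964 lower, and 52 to 195 higher at least 2-fold. Lists called by camera were 4 higher and 3 lower over all 6 libraries (of 17) and 4 higher and 5 lower in the 5 libraries (of 18). With an estimated correlation 0 were called in each direction in either comparison, and fry called 1 higher over all 6 libraries. With 1 library left out the 6-library comparison called 4 to 6 lists higher and 3 to 5 lower, quality weights called 5 lower, and the 5-library comparison called 2 to 4 higher. Mitochondrial respiration genes reversed from a median of 0.349 to -0.254 without the library labelled siUsf2 3 and to -0.262 with quality weights, and ranged up to 0.595 without siUsf2 2. Without siUsf2 1 or 2 lysosome genes were called higher in the 6-library comparison too (adjusted p = 0.0268 and 0.0397), and mitochondrially encoded transcripts lower (adjusted p = 0.0333 and 0.00559). The cause of these differences was not tested, except where leaving out or weighting down the library labelled siUsf2 3 made them by construction. Of the values of named genes in the 5 libraries, 1279 kept their side of the threshold under the alternatives, 52 lost the call and 49 gained one. For the 6-library comparison these were 1500, 72 and 154. In both comparisons together 22 values of named genes differed in sign from the reported value, each not called in either setting. At a depth of 3414565 counts, a count of 0 in the library labelled siUsf2 3 allows a level of up to 0.879 CPM.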

Other observations

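The hypoxia and NF-kappaB lists in this part were written after the main results were seen, but before the values of their members were. Chosen only after the result was seen were the tests of read assignment, of a wrong label and of fewer differentiated cells, the counts over other splits, and the 5-library comparison on which most tests rest.

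Car9, Ndrg1, Apln, Slc2a1 and Bnip3, which hypoxia is known to induce, were all higher in siUsf2 1 and 2, at log2 fold changes of 1.38, 0.77, 0.99, 0.47 and 0.55, though the call of Bnip3 ended without siControl 1 (adjusted p = 0.0799) and without siControl 2 (adjusted p = 0.0806). Ndrg1 and Apln were chosen after their values were seen. The hypothesis that other hypoxia-inducible genes rise with them was tested on 20 further genes. Of these, 10 rose and 1 fell in the 5 libraries by edgeR, with a median log2 fold change of 0.396, and the list was higher by camera (adjusted p = 1.54e-06; adjusted p = 0.025 with an estimated correlation), adjusted over the hypoxia and NF-kappaB lists alone. Adjusted together with the fixed lists, 20 in all, these became 3.86e-06 and 0.125, so with an estimated correlation the call does not hold over all lists. Pfkfb3, a glycolytic regulator, rose by 0.93 (SE 0.15), Eno2 by 0.69 (SE 0.11), Pdk1, which restrains pyruvate oxidation, by 0.49 (SE 0.09) and Adm by 0.95 (SE 0.31), while Stc2, the member that fell, was at -0.99 (SE 0.20). Vegfa, at 0.17 (SE 0.08, edgeR adjusted p = 0.211), did not pass. Among the other members not called were Egln1 at 0.03 (SE 0.09, edgeR adjusted p = 0.889) and Kdm3a at -0.02 (SE 0.09, edgeR adjusted p = 0.926). Egln1 and Kdm3a are named here after their values were seen. The list median in the library labelled siUsf2 3 was 0.49, or 0.35 with pseudogene counts added to parent genes, a value that includes the shift of that library with exon density. Oxygen supply, cell density and other inducers of these genes were not measured, so a shared regulator remains a hypothesis.

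Il33, Ptgs2, Nos2, Ccl5, Ccl9 and Tnfrsf9 rose, the last by 1.95 (SE 0.31) from 1.41 ± 0.258 CPM (SD, n = 3), with Nos2, Ccl9 and Tnfrsf9 chosen after their values were seen. The hypothesis that other NF-kappaB target genes rise with them was not borne out: of 21 measured, none rose and 1 fell (Mmp13, chosen after its values were seen) by edgeR in the 5 libraries. Their median log2 fold change was -0.03 and camera did not call the list (adjusted p = 0.685). Il6, Nfkbia and Cxcl1 were at -0.26, -0.10 and 0.07.

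The library labelled siUsf2 3 stood apart from the others while most responses of siUsf2 1 and 2 were visible in it. A lower depth is argued against, since siUsf2 1 thinned to its total still correlated with siUsf2 2 at 0.9925, though depth took part of the gap in detected genes (20697 after thinning). A control library under a wrong label is argued against too. The set was 284 protein-coding genes without a paired pseudogene that changed at least 2-fold in siUsf2 1 and 2. Of these, 93.7% lay on the same side of the siControl mean in the library labelled siUsf2 3 (95.2% of the higher, 93.2% of the lower). Each siControl library set against the other siControl libraries gave 40.5% to 58.1%. Over all 359 genes changed at least 2-fold the share was 88.9%, against 42.6% to 57.9% for the siControl libraries. The siControl shares are a rough yardstick, since they have fewer controls and these libraries helped to choose the genes. Reads of genes with pseudogene copies may have been assigned differently before deposit, in this library or in the others. Which assignment is the right one was not tested. Over 899 families the pseudogenes in the library labelled siUsf2 3 lay at a median log2 ratio of -3.98 to siUsf2 1 and 2. Parent genes lay at 0.61, and their sum at -0.159. With pseudogene counts added to parent genes the library still correlated with the others at 0.9411 to 0.9443, against 0.9912 to 0.9965 among the other pairs. Adding these counts therefore left part of its distance unaccounted for. The sum covers only paired pseudogenes, so it cannot tell whether a different assignment accounts for the rest. The Usf2 level of this library stays open. Usf2 and Usf2-ps1 together held 30.8 CPM there, against 19.4 to 21.2 CPM in siUsf2 1 and 2 and 27.3 to 40.7 CPM in siControl. Over all 6 libraries this sum had a log2 fold change of -0.54 (SE 0.21, edgeR adjusted p = 0.351). The log2 ratio of Usf2 (0.88) was at percentile 93.6 of protein-coding genes with similar exon density and no paired pseudogene. Usf2 itself has a paired pseudogene, so these genes are an unlike set. Among the parent genes of the 899 families the upper quartile was 1.54, and for the sums of parent and pseudogenes it was 0.121.

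The lower muscle differentiation genes could in part reflect how reads were counted or a trend with sequence composition, and both are argued against as the whole cause. With pseudogene counts added to parents the list median was -2.096, and after removal of a trend on GC content and transcript length it was -1.989. Fewer differentiated cells in the siUsf2 cultures would lower every member, and 100% of the 29 measured members lay below the siControl mean. The quartiles of their log2 fold changes were -2.77 and -1.26. A limit on this spread, for 1 common factor, was added to the test after every member had been seen to lie below, and the spread exceeded it. The spread cannot decide the question, because members may differ in their level in undifferentiated cells, which was not measured. Whether fewer cells expressed these genes or each cell expressed less cannot be told apart in RNA pooled from many cells. A direct action of USF2 on these genes stays open as untested. In the library labelled siUsf2 3, 21 of the 29 members lay below every siControl library and 5 above, although its measured Usf2 level was within the siControl range. How far the fall of these genes depends on the Usf2 level therefore also stays open.

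The lower interferon response genes may reflect an effect on the siControl side. A single siControl library with high interferon genes is argued against, since the highest list median with 1 siControl library left out was -1.373 (without siControl 3; -1.378 and -1.462 without siControl 1 and 2), with 19 or 20 members that fell. A response to the control siRNA itself cannot be told apart from a fall after Usf2 knockdown, as 0 untransfected libraries are in the series used here. The GC and length trend left the list median at -1.51.

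The real split of the 6 libraries called 7 genes and the highest of the other splits 0, and only 1 of 10 splits reached the real count. In the 5 libraries the real split called 1957 genes and the highest of the other splits 88, again 1 of 10. With 10 splits a share below 0.05 cannot be reached.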
